A study of Mus musculus with 2 samples.

How the data were processed

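Droplet single-cell RNA profiles (10x Chromium, 3' chemistry) of mouse liver cells from 2 libraries were analysed. The authors deposited counts: the values are UMI counts per gene and barcode, whole numbers with no normalization, and gene and barcode lists are given as text with no unit (other). The matrix headers name Cell Ranger 5.0.1, and the submitters' processing notes name Cell Ranger 6.0.1, Seurat 4.0.1 and build mm10; which version made the matrices was not settled. The notes also list STAR 2.5.2b, HTSeq 0.6.0, cutadapt 1.14, Trimmomatic 0.36 and UMI-tools, which serve data not used here. How the authors chose the barcodes is not given in the sources used here. EGFP in the DDC library and tdTomato in the other were extra features. They were left out of the variable genes used for clustering and of the class totals in the comparisons. Library totals, the cell filter, the scaling before clustering, thinning and the EGFP CPM values included them.

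The DDC library held 8694 barcodes and 104523363 UMIs, and the DDC and cMet library 18316 barcodes and 186997180 UMIs. Barcodes with at least 500 genes, at least 1000 UMIs and at most 30% mitochondrial UMIs were kept: 3613 (41.6%) and 12593 (68.8%), with medians of 20397 and 3529 UMIs and 4405 and 1391 genes. Of these, 25.1% and 47.0% had under 3000 UMIs. Scrublet (in scanpy, default settings) marked 0 doublets in both libraries, so the caller did not work, no cell was left out, and doublets remain possible in clusters with markers of several classes.

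Each library was clustered on its own: counts scaled to 10000, log-transformed, 2000 variable genes without mitochondrial, ribosomal and fixed-list genes, 30 principal components, a graph of 20 neighbours and the Leiden method at resolution 1. Classes were named from 116 markers of 12 classes fixed before the data were examined, as were 34 gene lists, the named-gene rule and the comparisons. The scoring rule was set after the clusters were seen. A class needed at least 3 of its markers and no fewer present than absent, each at least 2-fold above the other cells and in at least 10% of the cluster's cells; hepatocyte markers had to be at least 4-fold above the median of non-epithelial clusters. A cluster whose 10 leading genes went against the name stayed unnamed, as did a shallow cluster (median UMIs over 3 times below its library's) with none of its markers among those that lead against all other cells. Whether leading genes went against a hepatocyte name was judged against non-epithelial clusters. Judged against all other cells, 2 clusters with 43.7% of the class in the DDC library and 2 with 19.1% in the other were led by markers of another class, and leaving them out is an alternative chosen after seeing the data. The progenitor-like class of the DDC and cMet library joins cluster 8, with 4 of 8 markers, and cluster 15, with 6.

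UMIs were summed over a class and scaled by the class total to CPM, and a log2 ratio taken for genes with at least 50 UMIs. A side with 0 UMIs was set at a floor of 3 UMIs over the class, so the ratio is a bound. Intervals were exact Poisson for sums, and Clopper-Pearson for shares, at 95%. A list's median was placed among 10000 random lists matched on expression in 20 bins; lists beyond the 2.5 and 97.5 percentiles are called outside the range. With 1 library per group there is no p-value, standard error or count of changed genes. The named genes are the 12 highest and 12 lowest with at least 50 CPM on a side, without mitochondrial, ribosomal, marker and unnamed genes and without genes over 3 times higher in another class (possible free RNA), and up to 4 members per list with the largest ratio. Some of these genes are not reported here.

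Shares of cells with a UMI were taken after thinning each cell to 2000 UMIs without replacement. On simulated counts with 200 genes changed by known folds, intervals for unchanged genes covered the truth for 95.6%, 95.8% and 95.5% of genes in the 3 main comparisons; for changed genes the share ran from 85.4% to 100% over groups of about 50 genes. Alternatives were the cell filter, clustering resolution, list genes in the clustering, joint clustering, scaling, the UMI minimum and thinning; leaving out the highest 5% of doublet scores and keeping the shallow clusters were also chosen after seeing the data. Comparing progenitor-like with hepatocyte-like cells in the DDC and cMet library was added then as well. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, scanpy 1.11.5 and matplotlib 3.10.9.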

Results

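The series asks how hepatocytes, the liver progenitor-like cells that appear under a biliary diet injury, and cells of a liver tumour model differ in their transcriptomes. DDC is a diet that blocks haem synthesis and injures the bile ducts. By its label, the tumour model adds the MET receptor gene (cMet). The DDC library pooled cells of untreated mice at day 0 with cells of Sox9-EGFP mice after 2 weeks of diet. The DDC and cMet library pooled cells of untreated mice at day 0 with cells of tumour-model mice after 5 months. There were 2 mice per time, and the deposited barcodes do not separate mice or times, so each library is 1 sample and a mixture. The DDC library held 104523363 UMIs in 8694 barcodes and the DDC and cMet library 186997180 UMIs in 18316 barcodes. Intervals are 95% intervals for counting error alone. There is no replicate, and library and condition cannot be told apart.

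Hepatocyte-like cells made up 1573 of 3613 cells (43.5%, interval 41.9 to 45.2) in the DDC library and 8066 of 12593 (64.1%, 63.2 to 64.9) in the DDC and cMet library. Progenitor-like cells, named from Sox9, Spp1, Cd24a and related markers, were 333 (9.22%, 8.29 to 10.2) and 729 (5.79%, 5.39 to 6.21). Macrophage-like cells were 261 (7.22%) and 1112 (8.83%), and endothelial-like cells 65 (1.80%) and 309 (2.45%). Monocyte- or dendritic-like cells numbered 18 and 67, and T- or NK-like cells 22 and 0. No cluster carried enough markers for a tumour-hepatocyte-like or erythroid-like name. Markers of other classes reached the rule only beside those of another class, whose name was given or which left the cluster mixed or unnamed: cholangiocytes in DDC and cMet cluster 15, neutrophils in DDC cluster 13, B cells in DDC cluster 20 and DDC and cMet cluster 19, stellate cells in DDC cluster 16 and DDC and cMet clusters 9 and 16, and T or NK cells in DDC and cMet cluster 17 (122 cells). Clusters with markers of several classes held 171 cells (4.73%) and 1933 (15.3%), and unnamed clusters 1170 (32.4%) and 377 (2.99%). These shares cannot be compared in direction, because the naming left more hepatocyte-marker cells out of the class in the DDC library. Shallow clusters left out held 846 cells (23.4%) there and 0 in the other, where cluster 0 (2543 cells, median 1291 UMIs) was kept because depth was judged against the library's own median. With the shallow clusters kept, an alternative chosen after the data were seen, the shares were 67.0% and 64.1%. Clusters with hepatocyte markers but led by genes of another class held 246 (6.81%) and 37 (0.294%). With new clusters of cells with at least 1000 genes, 3000 UMIs and at most 20% mitochondrial UMIs, the shares were 56.5% and 48.4%.

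**Figure D1:**
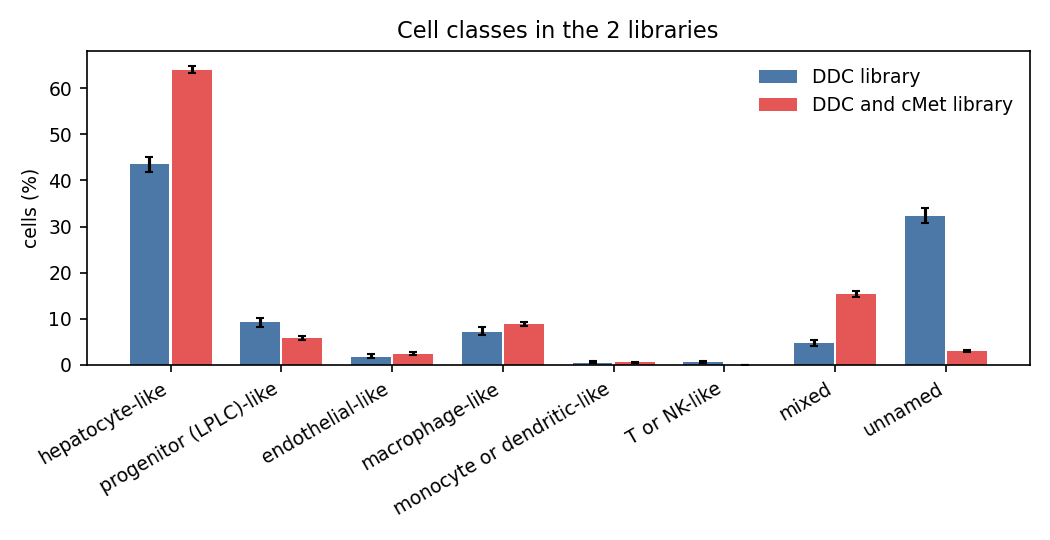
Percentage of cells (y axis) in each class in the DDC library (blue) and the DDC and cMet library (red), with 95% Clopper-Pearson intervals. Hepatocyte-like cells stood at 43.5% and 64.1%, and unnamed cells at 32.4% and 2.99%.

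The Sox9 reporter was common in hepatocyte-like cluster 4, but by CPM and at 2000 UMIs it was highest in the progenitor-like class. Sox9 and Spp1 helped to name that class and were not kept out of the clustering, so their higher shares there are partly built in. EGFP was kept out of both, but it reports Sox9 and is not independent of the name. The DDC library also pools untreated mice with Sox9-EGFP mice on diet, and barcodes do not separate them. A low EGFP share in a cluster may therefore reflect which mice its cells came from. EGFP reached 404 CPM in cluster 3, the progenitor-like cluster of the DDC library, 161 CPM in hepatocyte-like cluster 4 and 1.89 CPM in hepatocyte-like cluster 6. With every cell thinned to 2000 UMIs, 38.1% of progenitor-like cells (32.9 to 43.6) and 7.92% of hepatocyte-like cells (6.62 to 9.38) had an EGFP UMI, against 0 of 261 macrophage-like cells (0 to 1.40%); unthinned shares were 76.9%, 38.02% and 2.30%. Of the 122 hepatocyte-like cells with an EGFP UMI, 71 were in cluster 4 (22.9%; unthinned 79.0%), which is led by Spp1 and Tspan8, and the other hepatocyte-like clusters lay at 0% to 6.04%. Unnamed clusters 11 and 9 were at 23.7% (11.4 to 40.2) and 11.5% (6.55 to 18.2). Sox9, the transcription factor that marks biliary and progenitor cells, was seen in 39.6% of progenitor-like cells (34.3 to 45.1), 13.7% of hepatocyte-like cells (12.01 to 15.5) and 1.53% of macrophage-like cells after thinning. Epcam, a biliary adhesion molecule, was seen in 4.50%, 0.389% and 0%. Spp1, which encodes osteopontin, was seen in 95.8%, 54.1% and 26.8%, so its background is high. Krt19 was seen in 1 of 333 progenitor-like cells. Afp, a fetal liver gene, was at 2.40% and 1.95% against 1.92% in macrophage-like cells. At 4000 UMIs it was at 6.67% (4.22 to 9.92), 3.87% (2.94 to 4.98) and 3.50% (1.61 to 6.54), so hepatocyte-like cells are near background and progenitor-like cells are not settled; unthinned, Afp was at 35.1%, 19.1% and 17.6%. In the DDC and cMet library Sox9 was seen in 17.5% of progenitor-like, 2.71% of hepatocyte-like and 0.360% of macrophage-like cells, and Epcam in 5.22%, 0.125% and 0%. Thinning left out 32 and 3264 hepatocyte-like cells, 0 and 20 progenitor-like cells and 0 and 1 macrophage-like cells. Median depth was 51176, 38292 and 19458 UMIs for the progenitor-, hepatocyte- and macrophage-like cells of the DDC library, and 31967, 2695.5 and 13071 in the other; unthinned Sox9 shares were 97.9%, 66.9% and 8.43% in the DDC library and 61.6%, 11.4% and 2.52% in the other. Unthinned Spp1 shares in the DDC library were 99.7%, 96.9% and 88.5%, and those of Epcam 46.8%, 4.39% and 0.766%.

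**Figure D2:**
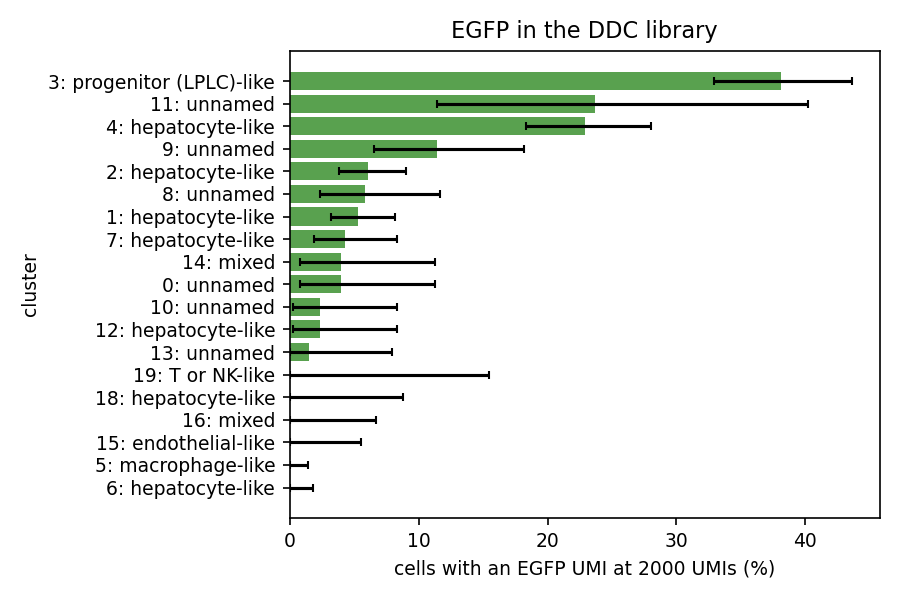
Percentage of cells with an EGFP UMI (x axis) in each cluster of the DDC library with at least 20 cells after thinning to 2000 UMIs, with 95% Clopper-Pearson intervals. Progenitor-like cluster 3 was highest, at 38.1%.

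Hepatocyte-like cells of the DDC and cMet library, set against those of the DDC library, had more RNA of bile acid, urea cycle, gluconeogenesis and periportal genes and less of the p53, cytoskeletal and chemokine genes. Bile acid synthesis and uptake genes were higher for 14 of 15 (list median log2 ratio 0.82), among them the transporters Slco1a1 (3.45) and Slc10a1 (2.49) and the enzyme Cyp8b1 (2.80). All 7 urea cycle genes were higher (0.75; Asl 1.36, Arg1 1.25), as were 9 of 10 genes of gluconeogenesis and amino acid breakdown (0.85; Hpd 1.96, Tdo2 1.502) and 8 of 12 periportal genes (1.06; Etnppl 2.76, Cyp2f2 1.89). Of the p53 targets, 9 of 10 were lower (median -1.63): Phlda3 -4.45, Eda2r -4.46, the cell cycle inhibitor Cdkn1a (ENSMUSG00000023067, chromosome 17 from 29090976 to 29100727 in mm10) -3.57 (17.2, 16.5 to 18.0, against 205, 201 to 208 CPM) and Bax -1.88, while Btg2 went the other way. Cytoskeleton, keratin and annexin genes were lower for 14 of 16 (-1.47; S100a6 -3.03, Anxa2 -2.32) and epithelial chemokines for 6 of 7 (-1.82; Ccl2 -3.68), with Cxcl2 at 2.93.

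Other lists in the same comparison also lay outside the range of random lists. All 14 mitosis genes were lower (-1.01; Nusap1 -1.42), as were 14 of 16 NRF2 and glutathione genes (-0.69; Cbr3 -2.12, Srxn1 -1.34). Summed UMIs weigh deep clusters most. In the DDC and cMet library cluster 1 held 54957872 of the 116260788 UMIs, and 0 of its 1437 thinned cells were cycling. Counted per cell at 2000 UMIs, the cycling shares given below overlap in their intervals (4.72 to 7.13 and 4.09 to 5.30%). The mitosis median and these shares thus weigh the clusters differently. Male-biased genes were higher for 7 of 9 (2.19; Selenbp2 4.02, Cyp4a12a 3.58) and female-biased genes for 4 of 6 (1.54). Lipogenesis was higher for 6 of 10 (0.35; Thrsp 4.06, Scd1 1.27), xenobiotic P450 genes for 8 of 11 (0.31; Cyp2c54 2.86), immediate early and heat shock genes for 10 of 14 (0.40; Atf3 1.63) and hepatocyte transcription factors for 9 of 14 (0.13; Ppara 1.67); the last list turned to -0.13 in thinned cells, and to -0.10 without the 4 clusters named below. The immediate early and heat shock list was mixed, with a mean of -0.0085 and its lowest member at -3.12. Medians inside the random range were -0.52 for pericentral genes, -0.65 for basolateral efflux, -0.05 for haem genes, -0.23 for YAP targets, -0.34 for the Notch pathway, -0.56 for Wnt targets, -0.14 for MET and MAPK outputs and -0.38 for DNA replication. The rest inside it were acute phase -0.43, metallothionein and metal -0.19, glycolysis -0.31, cholesterol synthesis -0.39, fatty acid oxidation 0.08, unfolded protein response -0.18, interferon -0.23, X and Y chromosome -0.11, lipid-associated macrophage -0.05, T cell exhaustion 0.85 and capillary endothelium 0.41.

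Single genes among the 12 highest were Mup11 (9.03), Inmt (5.78), C8a (5.77), Dbp (5.43), Mup18 (5.21), Hist2h2aa1 (5.01), Nnmt (4.51), Usp2 (4.50), Upp2 (4.49), Mup7 (4.30) and Thrsp (4.06). Inmt and C8a were also higher in progenitor-like cells (6.91 and 6.93) and macrophage-like cells (3.33 and a bound of 3.57). In the DDC and cMet library they stood at 13.3 and 6.72 CPM in macrophage-like cells, against 208 and 89.0 CPM in hepatocyte-like cells. Hepatocyte RNA carried into macrophage-like cells could give those values. Whether the shifts are particular to hepatocyte-like cells was therefore not settled. Dbp and Usp2 are known outputs of the circadian clock. The 12 lowest were Plet1 (-4.07), Hspb1 (-3.79), Defb1 (-3.58), Cdkn1a (-3.57), Serpina7 (-3.43), Sprr1a (-2.88), Cxcl9 (-2.87), S100a11 (-2.73), Mup17 (-2.68), Fat1 (-2.64), Lcn2 (-2.56) and Desi2 (-2.46). Spp1 (-3.77), Sox9 (-2.48) and Epcam (-1.29) were lower, but they are naming markers of other classes. Their values depend on which clusters carry the hepatocyte name. DDC cluster 4, with Spp1 among its leading genes, kept that name. DDC and cMet cluster 8, with Spp1, Plet1 and Serpina7 among its leading genes, was named progenitor-like. Alb was at 0.68, Hnf4a at 0.15, Mki67 at -0.33, Gpc3 at -0.36 and Afp, near background in the DDC library, at -1.13. Met was at 0.12, so the added gene is not visible as more Met RNA, and whether the counts can read it was not tested. The class was held by clusters 1, 2, 4, 6, 7, 12 and 18 in the DDC library and 0, 1, 2, 5, 6, 7, 11 and 18 in the other, and the median of all 13175 genes lay at -0.28. Against all other cells, DDC clusters 1 and 4 and DDC and cMet clusters 1 and 18 were led by tumour, progenitor or cholangiocyte markers; without them the medians were -1.16 for p53 targets, -1.11 for chemokines, 0.46 for bile acid genes and 0.13 for immediate early genes, and lipogenesis turned to -0.10. Defb1 and Sprr1a lead DDC cluster 1 and Serpina7 is among those that lead cluster 4; without the 4 clusters these were at -3.64, -3.00 and -2.80, Plet1 at -3.12, Cdkn1a at -2.98, Inmt at 4.64 and C8a at 4.63. Mup genes are near-identical in sequence, and Mup17 turned to 1.47 under the stricter cell filter.

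**Figure D3:**
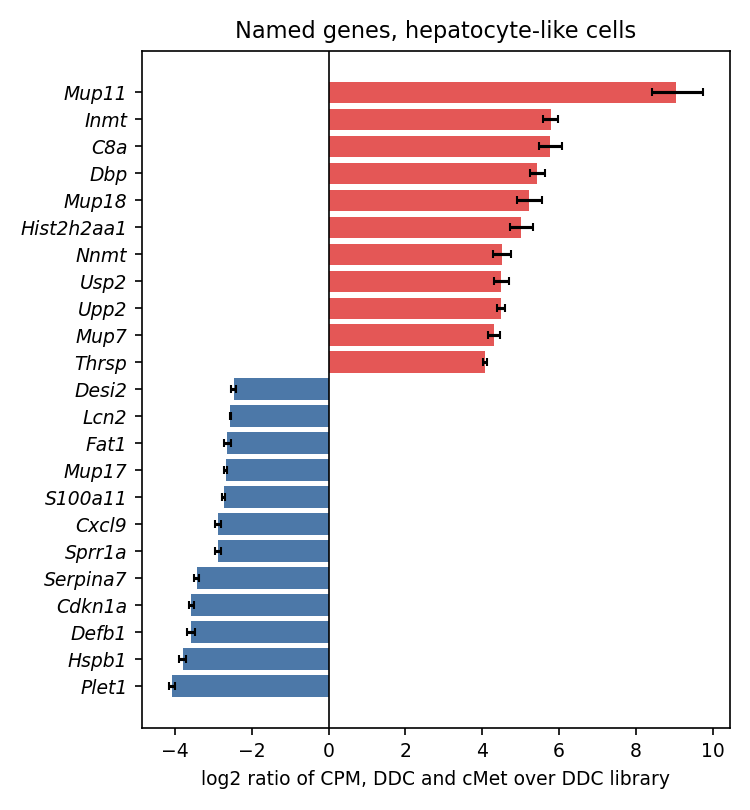
Log2 ratio of CPM (x axis), DDC and cMet library over DDC library, for the highest and lowest genes of hepatocyte-like cells, with 95% intervals for counting error. Values ran from Plet1 at -4.07 to Mup11 at 9.03.

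Within the DDC library, progenitor-like cells (cluster 3) had far less RNA of hepatocyte metabolism than hepatocyte-like cells, and more of the YAP, cytoskeletal and chemokine genes. All 10 measured YAP targets were higher (median 1.46; Ankrd1 6.05, Ccn2 5.13, F3 2.17), as were all 16 cytoskeleton, keratin and annexin genes (1.48; Anxa3 5.28, Vim 4.07, Tmsb4x 3.57) and all 8 epithelial chemokines (1.79; Cxcl5 4.98, Ccl2 2.89). All 10 p53 targets were higher (0.90; Phlda3 2.14, Bax 0.99), and the medians were 0.98 for MET and MAPK outputs (Fosl1 4.48, Etv4 3.96), 0.87 for immediate early genes (Junb 1.58) and 0.76 for interferon genes (Ifit3 3.45). Xenobiotic P450 genes had a median of -3.37 (Cyp3a11 -5.04, Cyp2c29 -5.54), bile acid genes -2.79 (Slc10a1 -4.81, Cyp7a1 -4.78), the urea cycle -2.06 (Arg1 -4.07, Cps1 -3.15), pericentral genes -2.00 (Cyp2e1 -4.72) and periportal genes -1.34 (Cyp2f2 -3.63). Lipogenesis (-1.33), gluconeogenesis (-1.27), acute phase (-1.24; Saa1 -3.52), cholesterol synthesis (-0.86), NRF2 and glutathione genes (-0.85; Gstm3 -3.74), and fatty acid oxidation (-0.55) were also lower. The medians of mitosis (-1.54; Ccnb1 -3.27) and male-biased genes (-3.40) each rest mostly on 1 comparator cluster. The mean log2 of CPM plus 1 of the mitosis list was 2.20 in cluster 3, 5.89 in mitotic cluster 7 and 0.73 to 1.17 in the other hepatocyte-like clusters. That of the male-biased list was 2.48 in cluster 3, 6.79 in cluster 12 (94 cells) and 2.58 to 3.40 in the others. Hnf4a, the central hepatocyte transcription factor, was at -0.42. The hepatocyte transcription factor list was at -0.02, just below the range of random lists (percentile 2.22). The median of all 12285 genes was 0.35, the MET and MAPK list turned to -0.80 in thinned cells, and the periportal list to 0.0510 with both libraries clustered together. Without DDC clusters 1 and 4 among the hepatocyte-like cells the chemokine median was 3.77.

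Within the DDC and cMet library no cluster met the tumour-like rule, so cluster 1, the hepatocyte-like cluster with most tumour markers (H19 and Tff3), was set against the other hepatocyte-like cells; that choice was made after the clusters were seen. Cluster 1 carried 2 tumour markers, and so did progenitor-like cluster 15, monocyte- or dendritic-like cluster 19 and macrophage-like cluster 20 of that library. That count therefore does not mark cluster 1 as tumour. The 1438 cells of cluster 1 had more RNA for cholesterol synthesis, with all 12 genes higher (median 0.71; Sqle 0.85), and all 13 interferon genes higher (0.33; Ifit1 1.38). Immediate early genes (0.56; Fos 0.95, Atf3 1.01), acute phase genes (0.33; Cp 0.87), YAP targets (0.51; Crim1 1.27), Wnt targets (0.54, from low counts) and hepatocyte transcription factors (0.25; Onecut1 1.17) were higher as lists, and Ccnd1, which encodes cyclin D1, was at 1.30. Mitosis genes had a median of -3.84 (Ccnb1 -5.47), male-biased genes -2.56 (Hsd3b5 -5.69, Mup1 -4.82), epithelial chemokines -1.17, cytoskeletal genes -0.42, periportal genes -0.37 (Cyp2f2 -1.66) and the urea cycle -0.31. Cyp7b1 was at -3.25 and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 1.34. Met (-0.08) hardly differed, and Afp was at 5.15 against 3.28 CPM. The comparison cells include mitotic cluster 6. They also include clusters 0, 5 and 7, with Mup genes among their leading genes. Cluster 7, whose leading genes also hold Cyp7b1 and Cyp2f2, had 23390039 of the 61302916 comparator UMIs. The mitosis, male-biased, Cyp7b1 and Cyp2f2 values may therefore rest on those clusters. The cytoskeletal and chemokine medians turned to 0.36 and 0.95 at the coarser clustering. The interferon median turned to -0.0821 at the finer clustering and to -0.14, with Ifit1 at -0.48, when list genes were used in the clustering. Cluster 1 is deep (median 37448 UMIs) and its comparators include clusters 0, 2 and 5, at 1291 to 2722 UMIs. The cholesterol median was 0.38 with cells thinned to 2000 UMIs and 0.47 as a mean over cells.

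**Figure D4:**
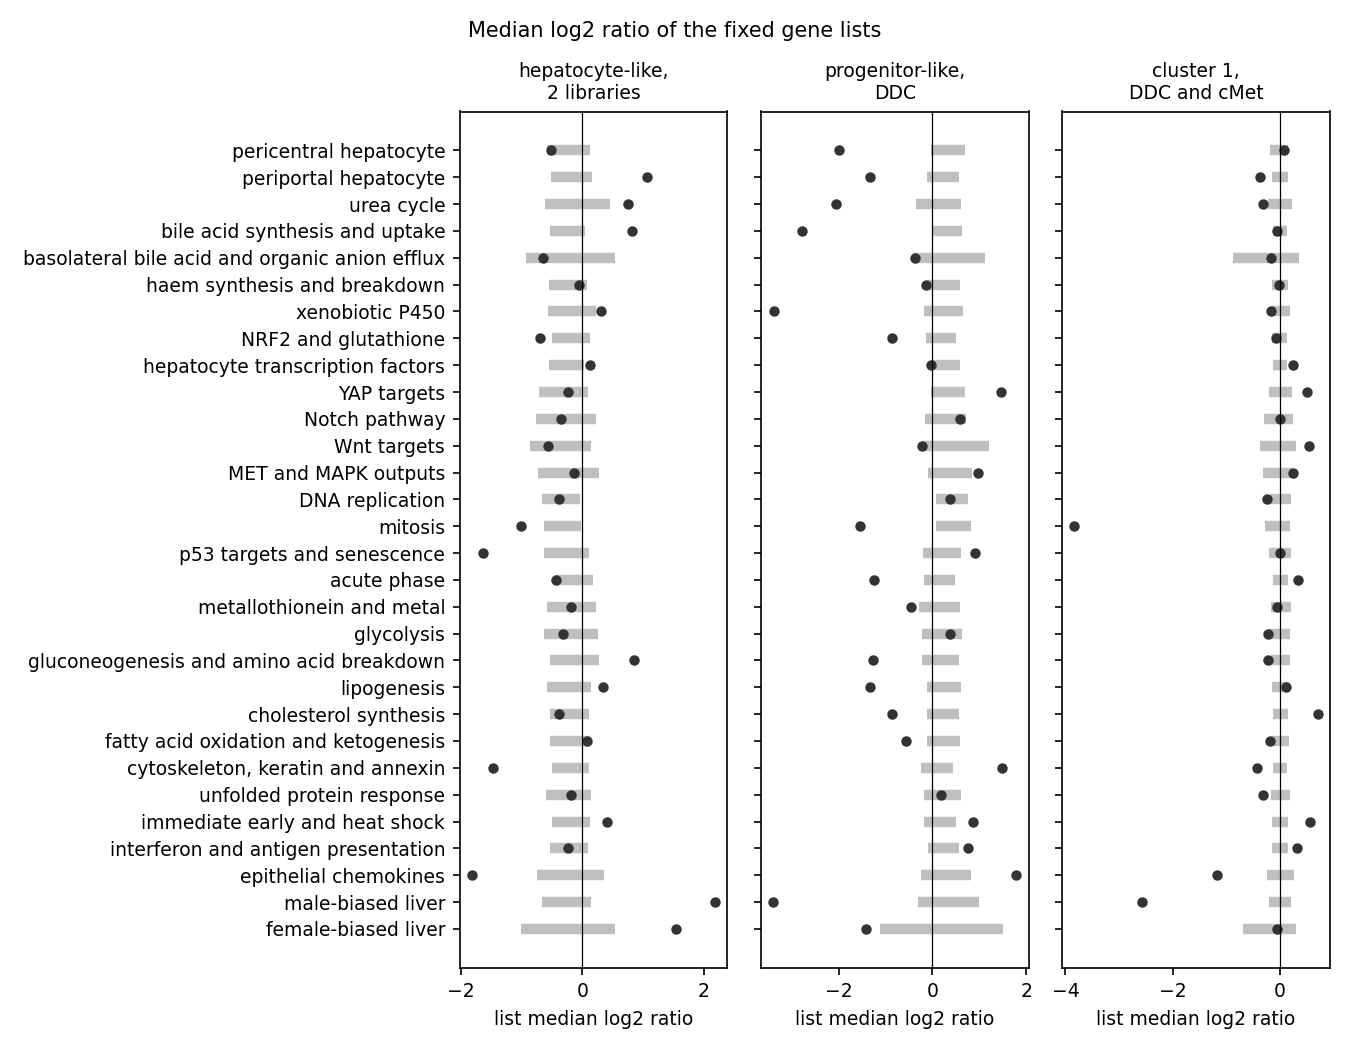
Median log2 ratio (x axis) of 30 fixed lists (dots) in 3 comparisons; grey bars hold the central 95% of 10000 random lists matched on expression. In cluster 1 the mitosis list was lowest, at -3.84.

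Set side by side, cluster 1 and the progenitor-like cells departed from hepatocyte-like cells of their own library partly in the same direction and partly not. YAP targets (0.51 in cluster 1 and 1.46 in progenitor-like cells) and immediate early genes (0.56 and 0.87) were higher in both. So were interferon genes (0.33 and 0.76) and MET and MAPK outputs (0.25 and 0.98), but in cluster 1 both lists turned under some alternatives. In progenitor-like cells the MET and MAPK list turned to -0.80 with cells thinned to 2000 UMIs. Lists lower in both included the urea cycle (-0.31 and -2.06) and periportal genes (-0.37 and -1.34). The medians of mitosis (-3.84 and -1.54) and male-biased genes (-2.56 and -3.40) were also negative in both, with the comparator limits given above. For mitosis, progenitor-like cells had a higher mean level than the DDC hepatocyte-like clusters other than mitotic cluster 7. A shared decrease in mitosis genes is therefore not shown. The difference in median, cluster 1 minus progenitor-like, was -1.90 for the cytoskeletal list (-0.42 and 1.48), -2.97 for epithelial chemokines, -0.95 for YAP targets and -0.90 for p53 targets; at the coarser clustering the first 2 lists were higher in both. Differences in the other direction were 3.20 for xenobiotic P450 genes, 2.73 for bile acid genes, 1.57 for cholesterol synthesis and 1.58 for acute phase genes. Each difference sets libraries made separately beside each other and was not tested.

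Cells with at least 2 UMIs over the mitosis list at 2000 UMIs were 5.84% of hepatocyte-like cells in the DDC library (4.72 to 7.13) and 4.66% in the DDC and cMet library (4.09 to 5.30). Progenitor-like cells were at 1.80% (0.664 to 3.88) and 1.13% (0.488 to 2.21), and macrophage-like cells at 5.75% and 5.31%. The cycling hepatocyte-like cells sat mainly in cluster 7 of the DDC library (44.9%) and cluster 6 of the other (31.2%); cluster 1 had 0 of 1437 (0 to 0.256%). Shares rose with depth, to 19.4% and 10.97% of hepatocyte-like cells unthinned, at median depths of 38292 and 2695.5 UMIs.

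Macrophage-like cells were the non-epithelial class with at least 100 cells in both libraries (cluster 5, and clusters 3 and 20). In the DDC and cMet library 8 of 9 lipid-associated macrophage genes were higher (median 0.77; Gpnmb 1.78, Fabp5 1.15, Trem2 1.05), as were 9 of 13 interferon genes (0.22; Isg15 2.75). All immediate early and heat shock genes were higher in these cells too, as given below, so cell handling stays open here as well. T cell exhaustion genes had a median of 0.60 over 3 genes and capillary endothelial genes -0.15 over 3, inside the random range. Hepatocyte lists moved with them (bile acid genes 1.505, periportal 1.09), and so did Alb (1.29). Of the barcodes, 50 were in both libraries, with 0 identical profiles.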

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

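Tests of the cluster mix, the scaling the macrophage-like cells, the shallow clusters and the clusters led by other markers for the p53 pattern, and of the comparator level and the scaling for the NRF2 pattern, were chosen only after the result was seen.

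NRF2 and glutathione genes, which protect against oxidative stress, were lower in progenitor-like than in hepatocyte-like cells of the DDC library (median log2 ratio -0.85) and higher in the DDC and cMet library (0.64), a difference of 1.49 that was not tested. The 2 clusters behind the name in the second library go opposite ways: cluster 8 at 0.73 and cluster 15, with more progenitor markers, at -0.44. The second median also turned negative under 5 alternative cell filters or clusterings, from -0.0248 to -0.44, so the opposite direction may come from which cells carry the name. The hepatocyte-like comparators differ too (-0.69, 14 of 16 genes lower) and may give part of it; as the whole cause they are argued against by the direct ratio of the progenitor-like cells (0.90), which rests mostly on cluster 8 (566 of 729 cells), and scaling by the smallest difference over other scalings (1.43). A difference between the libraries in cluster 8 stays open.

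The p53 list was lower in hepatocyte-like cells of the DDC and cMet library (median -1.63). Of its 8 hepatocyte-like clusters, 0 reached the lowest of the 5 larger DDC clusters. The highest mean log2 of CPM plus 1 was 4.03, against 4.73. DDC clusters 12 and 18, with under 100 cells, were left out of that count, and cluster 12 lay at 4.05. That count therefore does not settle a different mix of hepatocyte clusters. Without the clusters led by markers of another class the median was -1.16. The highest median over other scalings was -1.33, that of thinned cells -1.40 and that of macrophage-like cells -0.0863 (4 of 8 lower), which argue against scaling, depth and a difference in reading or mapping shared by all cells; progenitor-like cells had a like shift (-1.63, 9 of 10 lower). With the shallow unnamed clusters kept the median stayed at -1.63. The diet time, the age of the mice and cell handling stay open. So do the mix of hepatocyte clusters and the unnamed hepatocyte clusters led by genes of another class. Library and condition cannot be told apart.

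Epithelial chemokines moved opposite ways between the libraries, lower in hepatocyte-like cells of the DDC and cMet library (-1.82) and higher in its macrophage-like cells (1.73), a difference of 3.55 that was not tested. Without the hepatocyte-like clusters led by markers of another class the first median was -1.11. All 14 immediate early and heat shock genes were also higher in those macrophage-like cells (1.34), so cell handling stays open.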

How the results depend on the processing

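Alternatives that left out the highest doublet scores or hepatocyte-like clusters led by markers of another class, or kept the shallow clusters, were chosen only after the result was seen; so were the lists that stand for each comparison, picked from 34. No paired analysis was possible because the barcodes are not tied to mice. No alternative without doublet calls was run, since 0 cells were called. Of the leading values, 54 stayed within their counting interval and 55 moved. Of list medians, 1176 stayed, 922 moved and 33 turned direction; of named genes, 3251 stayed, 2613 moved and 34 turned. That a median stays is judged by resampling counts, a rule changed after the first run from a fixed distance. The p53 median ran from -1.68 to -1.16 and the YAP median from 1.06 to 2.07, each keeping its direction. In the values below the cause was not tested, shares are of cells and the rest are log2 ratios.

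At most 50% mitochondrial UMIs: progenitor-like share, DDC and cMet 5.13%, p53 -1.68. At least 1000 genes and 3000 UMIs, at most 20% mitochondrial UMIs: hepatocyte-like share, DDC 56.5%, hepatocyte-like share, DDC and cMet 48.4%, progenitor-like share, DDC and cMet 4.02%, cycling, DDC and cMet 5.42%, p53 -1.67, YAP 1.57, cholesterol 0.76, cytoskeleton difference -2.24. Leiden resolution 0.5: hepatocyte-like share, DDC 51.0%, hepatocyte-like share, DDC and cMet 66.8%, progenitor-like share, DDC and cMet 2.97%, cytoskeleton difference -1.04. Leiden resolution 2.0: hepatocyte-like share, DDC and cMet 72.7%, progenitor-like share, DDC and cMet 2.44%, YAP 1.65, cytoskeleton difference -2.51. Fixed-list genes used in the clustering: hepatocyte-like share, DDC 36.9%, progenitor-like share, DDC 6.42%, hepatocyte-like share, DDC and cMet 68.5%, progenitor-like share, DDC and cMet 2.99%, YAP 1.62, cytoskeleton difference -2.33. Both libraries clustered together: hepatocyte-like share, DDC 38.4%, progenitor-like share, DDC 18.4%, hepatocyte-like share, DDC and cMet 42.6%, progenitor-like share, DDC and cMet 0.945%, cytoskeleton difference -1.49. Highest 5% of doublet scores left out: hepatocyte-like share, DDC 46.7%, progenitor-like share, DDC 11.1%, hepatocyte-like share, DDC and cMet 65.8%, progenitor-like share, DDC and cMet 5.36%, p53 -1.68, YAP 1.60. Hepatocyte-like clusters led by markers of another class left out: p53 -1.16, YAP 2.07. Shallow clusters with hepatocyte markers kept: hepatocyte-like share, DDC 67.0%. Median-ratio scaling: p53 -1.33, YAP 1.10, cytoskeleton difference -1.56. 50 most abundant genes and mitochondrial genes left out of the total: YAP 1.35, cytoskeleton difference -1.79. Mean of each cell's CPM: cholesterol 0.47. Cells thinned to 2000 UMIs: YAP 1.06, cholesterol 0.38, cytoskeleton difference -1.72. No thinning: cycling, DDC 19.4%, cycling, DDC and cMet 10.97%, Sox9 share 97.9%. Thinned to 4000 UMIs: cycling, DDC 9.16%, cycling, DDC and cMet 7.53%, Sox9 share 63.0%. At least 3 UMIs: cycling, DDC 3.83%, cycling, DDC and cMet 2.54%.

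With at most 50% mitochondrial UMIs: progenitor-like, DDC and cMet, Wnt targets 0.0923; progenitor-like, DDC, Rsad2 -0.44. With at least 1000 genes and 3000 UMIs, at most 20% mitochondrial UMIs: cluster with tumour markers, xenobiotic P450 0.17; progenitor-like, DDC and cMet, NRF2 and glutathione -0.0248, Wnt targets 0.16; hepatocyte-like, Trem2 -0.14, Mup17 1.47; progenitor-like, DDC, Slco1a1 0.22. With Leiden resolution 0.5: cluster with tumour markers, cytoskeleton, keratin and annexin 0.36, epithelial chemokines 0.95, Cbr3 0.0735, Cxcl16 0.21, Ccl2 1.40; progenitor-like, DDC and cMet, NRF2 and glutathione -0.16, Wnt targets 0.15; hepatocyte-like, Axl -0.92, Lfng -0.72, Hk2 -1.76, Pkm -0.73, Trem2 -0.66, Mmp12 -0.12, Havcr2 -1.22, Entpd1 -0.39. With Leiden resolution 2.0: cluster with tumour markers, xenobiotic P450 0.16, MET and MAPK outputs -0.29, interferon and antigen presentation -0.0821, Oat 0.0592, Ajuba -0.0152; progenitor-like, DDC and cMet, NRF2 and glutathione -0.18, Wnt targets 0.17. With fixed-list genes used in the clustering: cluster with tumour markers, xenobiotic P450 0.12, MET and MAPK outputs -0.36, interferon and antigen presentation -0.14, Oat 0.32, Ajuba -0.0504, Ifit1 -0.48, Gpc3 -0.00543; progenitor-like, DDC and cMet, NRF2 and glutathione -0.27, Wnt targets 0.14. With both libraries clustered together: progenitor-like, DDC, periportal hepatocyte 0.0510, hepatocyte transcription factors 0.00665, Pkm -0.86, Gpnmb -0.00574, Plvap -0.00952; progenitor-like, DDC and cMet, NRF2 and glutathione -0.44, Wnt targets 0.77; hepatocyte-like, Axl -0.24, Lfng -0.51, Hk2 -0.50, Pkm -0.27, Trem2 -0.28, Havcr2 -0.60. With highest 5% of doublet scores left out: progenitor-like, DDC and cMet, Wnt targets 0.0277; hepatocyte-like, Hspa1a 2.26; progenitor-like, DDC, Hspa1a 1.97, Hspa1b 0.69. With hepatocyte-like clusters led by markers of another class left out: hepatocyte-like, hepatocyte transcription factors -0.0984, lipogenesis -0.10. With mean of each cell's CPM: hepatocyte-like, hepatocyte transcription factors -0.0635, Hspa1a 0.37; cluster with tumour markers, xenobiotic P450 0.10, MET and MAPK outputs -0.0764; progenitor-like, DDC and cMet, Wnt targets 0.32. With no minimum of UMIs: progenitor-like, DDC, Wnt targets 0.0458; progenitor-like, DDC and cMet, Wnt targets 0.12. With cells thinned to 2000 UMIs: hepatocyte-like, hepatocyte transcription factors -0.13; progenitor-like, DDC, MET and MAPK outputs -0.80.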

Other observations

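Tests of Hist2h2aa1, tdTomato and the Mup sum without Mup20 were chosen only after the result was seen.

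Clock genes differed between the libraries, with the median of the 7 genes that rise by day at 2.67, 2.04 and 2.08 in hepatocyte-, progenitor- and macrophage-like cells. In hepatocyte-like cells of the DDC and cMet library Dbp (5.43), Usp2 (4.50) and Upp2 (4.49) were among the 12 highest genes, Per3 was at 3.70, Ciart at 4.94 and Tef at 2.78, while Arntl (-5.21) and Npas2 (-5.47), which peak in the opposite phase, were lower. A candidate explanation is the time of day at which the livers were taken. In macrophage-like cells Tef, Hlf, Per2, Per3, Nr1d1, Nr1d2 and Ciart had a median of 2.08, which is 2.51 above the median of Arntl, Npas2, Clock, Nfil3 and Cry1; a time-of-day difference needed over 1. Hepatocyte RNA carried into those cells could give part of this and cannot be told apart: the second median was -0.43, between the bounds set for it, although Arntl alone was at -1.43 (-1.89 to -0.97), and Usp2 was at 0.09. No sampling time is given in the sources used here, and genes that follow the clock or feeding may differ between these libraries for that reason.

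Progenitor-like cells of the DDC and cMet library, against hepatocyte-like cells of that library, had more chemokine RNA (median 3.10; Ccl20 6.04, Ccl2 5.25), cytoskeletal RNA (1.86; S100a6 5.35), YAP targets (1.29; Ankrd1 4.81) and p53 targets (1.07; Phlda3 2.98), and less for xenobiotic P450 (-1.73) and bile acid genes (-1.23). In macrophage-like cells of that library all 14 immediate early and heat shock genes were higher than in the DDC library (1.34; Atf3 2.96, Hspa1b 2.15).

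Hist2h2aa1 was higher in the DDC and cMet library in hepatocyte- (5.01), progenitor- (4.48), macrophage- (1.79) and endothelial-like cells (2.73, 0.17 to 8.07, from 1 UMI on the DDC side). The largest distance from hepatocyte-like cells, 3.22, argues against a difference in reading or mapping of equal size in macrophage-like cells for Hist2h2aa1, and a smaller shared part stays open. C8a and Inmt were also higher in progenitor- (6.93 and 6.91) and macrophage-like cells (a bound of 3.57, and 3.33). Both had 0 UMIs on the DDC side in endothelial-like cells. No test was set for these genes, so a shared difference in reading or mapping stays open for them. Hepatocyte RNA carried into macrophage-like cells stays open as well. The 18 measured Mup genes ran from -2.68 to 9.03 while their summed UMIs differed by 0.78. Mup20 alone held 79.2% of the DDC sum, and without it the sums differed by 2.15, so reads shared between near-identical genes and a real difference cannot be told apart.

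tdTomato had 2 UMIs in 2 barcodes, against 11619 EGFP UMIs in 1155 barcodes of the other library. With so few UMIs the shares decide nothing: 0% of macrophage-like and endothelial-like cells had one, and the highest share in any class was 0.274%. Progenitor-like cells were 5.79% of cells but 0.945% under joint clustering. Recombination in Sox9-expressing cells, few cells from transgenic mice and a sequence not captured by the assay therefore cannot be told apart.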
